A study of Mus musculus with 6 samples.

How the data were processed

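The data were RNA-seq values of mouse testis from 6 libraries, 3 from mice on an ethanol liquid diet and 3 from mice on a control liquid diet, all at 16 weeks. Per the labels' protocols, libraries were made with a stranded total RNA kit after ribosomal RNA was removed. Reads were aligned with HISAT2 to mm10, per the submitters' processing notes. The version of HISAT2, the counting tool, its strand setting and the annotation release are not given in the sources used here, so that values of overlapping or antisense genes, and of near-identical copies such as the globin genes Hba-a1 and Hba-a2 or the histone genes, are uncertain.

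One table held every library. Its read counts per gene were whole numbers, deposited without normalization, per the file headers. FPKM, fragments scaled to transcript length and library size, and TPM, in which each library has the same sum, were computed by the authors and stood beside the counts, per the file headers. The table listed 45777 genes with symbols and Entrez Gene IDs, every row named a gene, and there were 0 sample columns outside these 6 libraries. Total counts ranged from 38935654 to 47420249 per library. Groups and replicate numbers came from the labels. In each of the 15 pairs of libraries the counts differed by more than sampling noise, with a chi-square per gene of at least 7.66 where 1 is expected, so that no library was counted once for a pair.

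The main test ran on the counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by TMM, and the diets were compared by the quasi-likelihood F-test with no covariate and Benjamini-Hochberg adjustment. Of the 45777 genes, 25073 were tested. The common dispersion was 0.0104, a biological coefficient of variation of 0.102. CPM values are TMM-scaled and given as mean ± SD over 3 libraries. Standard errors of log2 fold changes were computed from the fold change and its F statistic. Single values were compared by exact two-sided permutation tests. Coordinates came from an NCBI gene table of the mm10 assembly, 1-based, in which 24998 of the tested genes were found by Gene ID.

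The test, 38 gene lists, a panel of 27 genes and the rule for naming genes were chosen before the data were examined. Lists covered germ cell stages, supporting and interstitial cells, other cell types that the tissue can hold, and pathways of ethanol metabolism, stress, lipid metabolism and gene regulation. A list was tested with at least 5 measured members by camera on the edgeR fit, with a preset correlation of 0.01, and again with an estimated correlation and by fry (limma 3.58.1). P-values were also adjusted over each list alone. The naming rule took, in each direction, the 12 genes of largest fold change past an adjusted p of 0.05, filled to 8 with the genes of smallest p that had a mean of at least 1 CPM, no overlap between the diets and a symbol other than that of a predicted gene. It also took up to 4 members of smallest p from each list described, and the panel, in the text or as a count. Any other gene named was chosen after its values were seen: Kitl, Amh, Col1a1, Col1a2, Fdx1, Plin2, Lpl and Adipoq as list members, and the genes said so elsewhere.

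Alternatives were RLE factors, upper-quartile scaling, total counts alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1), log2(TPM + 1), log2(FPKM + 0.1) and log2(TPM + 0.1), the replicate number as a block, a threshold of 0.1, removal of mitochondrial and globin genes, and each library left out in turn. Added after the data were seen were offsets for GC content and transcript length, a term for libraries that share a trend with transcript length, protein-coding genes alone, and the estimated correlation without ethanol library 1. GC content came from GENCODE M21 transcripts. Transcript length was derived from the deposited counts and FPKM, so it is not independent of these data. Both were found for 17357 of the tested genes. In the list of lymphocytes and granulocytes 70% of members had a value, so that this check is void for that list; it is above 80% in the others.

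The procedure was tested on simulated data drawn from the means, dispersions and library sizes of this comparison, over 24662 genes, in which 200 single genes and the members of 2 lists were changed. Of 50 genes changed at each size, it recovered 6% at 1.25-fold, 66% at 1.5-fold, 90% at 2-fold and 100% at 4-fold. It made 143 calls in all, 7 of them of genes that had not been changed. Both shifted lists were called, 1 raised by 1.2-fold and 1 lowered by 1.1-fold, and 1 list that had not been shifted. In 5 simulated comparisons without change it called at most 4 genes and 0 lists. Simulated genes were drawn independently of one another and without structure among the libraries. These counts therefore do not measure false list calls, or how often a true change is detected, in the real data. There, splits of the libraries that mix the diets called 4 to 10 lists.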

Results

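Total RNA from the testes of wild-type mice was sequenced after 16 weeks on a liquid diet with ethanol or on the control liquid diet, to ask how chronic ethanol intake affects the testis transcriptome. Each diet had 3 libraries, prepared with a stranded kit after removal of ribosomal RNA. Total counts were 47420249, 44138842 and 43389811 in control libraries 1, 2 and 3, and 38935654, 43399317 and 41159720 in ethanol libraries 1, 2 and 3, without a difference past the exact two-sided permutation test (n = 3, p = 0.2, where 0.1 is the smallest p that 3 against 3 allows). Protein-coding genes took 93.2 ± 0.30% of the counts in controls and 93.4 ± 0.36% with ethanol, and mitochondrially encoded genes 0.860 ± 0.059% and 0.923 ± 0.076%. The median standard error of a log2 fold change was 0.09 over the 13229 genes with a mean of at least 5 CPM, the read count scaled to library size. Nothing in the labels says that the libraries of a diet came from separate animals, so p-values measure only the spread between these samples, which may be technical.

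The ethanol-fed testes showed small shifts that ran in opposite directions in Sertoli cell genes and in genes of meiotic and round germ cells. Genes of Sertoli cells, which nurse the germ cells in the seminiferous tubule, rose as a group relative to other genes, with a median log2 fold change of 0.22, and so did extracellular matrix genes, with a median of 0.29 (camera adjusted p = 2.28e-10 and 1.34e-08 with a preset correlation between genes; 0.278 and 0.346 with an estimated correlation, which calls neither). Genes of meiosis, of round spermatids and of the sperm tail fell as groups, with medians of -0.07, -0.09 and -0.06, and these calls too were lost with an estimated correlation (camera adjusted p = 0.346, 0.437 and 0.346). On log2(TPM + 1) their medians were closer to 0, at -0.011, -0.021 and -0.013, on a scale where the median of all genes was itself 0.044 against 0.0065 on TMM-scaled counts; meiosis was not called there (camera adjusted p = 0.0797). Among single genes, Cyp11a1, which encodes the enzyme that starts steroid hormone synthesis, was at 58.1 ± 14.4 CPM in controls and 23.5 ± 8.94 CPM with ethanol (SD, n = 3), with a log2 fold change of -1.30 (SE 0.24). It did not pass the test over all genes, with an edgeR adjusted p of 0.127.

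No single gene passed that test in either direction. Of 25073 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 higher and 0 lower, and the lowest adjusted p was 0.0515. At an unadjusted p under 0.05 there were 3343 genes, 1867 higher and 1476 lower, where 1254 are expected with independent genes and no structure among the libraries; a split that mixes the diets, control libraries 1 and 3 and ethanol library 3 against the rest, gave 3133. The 3 libraries of one diet lay above all 3 of the other for 4707 genes, or 18.8%, where chance gives 10% without structure among the libraries. This share was not computed for splits that mix the diets. On the same counts DESeq2 called 203 genes higher and 127 lower, and limma-voom 3 and 2. Gene values given from here on are therefore values of genes not past edgeR's threshold over all genes, unless a setting is named, and only gene lists are said to rise or fall.

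Among genes with a mean of at least 1 CPM, no overlap between the diets and a symbol other than that of a predicted gene, the 8 of smallest p on the higher side were Nmnat3, Serpina3a, Aldh1l1, Alas2, Elmo1, Irf8, Try5 and Lamc3. Nmnat3 (Gene ID 74080; chromosome 9, 98287433 to 98420533 on mm10), an enzyme of NAD synthesis in mitochondria, was at 29.1 ± 0.54 CPM in controls and 48.0 ± 5.80 CPM with ethanol, a log2 fold change of 0.72 (SE 0.09, edgeR adjusted p = 0.0515), and passed without ethanol library 2 (adjusted p = 0.0262). Serpina3a, a member of the serine protease inhibitor family, had a log2 fold change of 0.62 (SE 0.09, edgeR adjusted p = 0.0765). Aldh1l1, an aldehyde dehydrogenase of folate metabolism, was at 32.7 ± 1.88 CPM in controls and 46.4 ± 1.18 CPM with ethanol, and Alas2, the first enzyme of heme synthesis in erythroid cells, at 16.6 ± 0.38 and 24.7 ± 1.95 CPM. Log2 fold changes were 0.43 for the engulfment adaptor Elmo1, 0.91 for Irf8, a transcription factor of myeloid cells, 0.74 for the trypsin gene Try5 and 0.39 for the laminin chain Lamc3. The predicted gene Gm41370, named after its values were seen, had a smaller p than any of these 8, at 1.21 ± 0.083 CPM in controls and 3.33 ± 0.30 CPM with ethanol (edgeR adjusted p = 0.0515).

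Under the same conditions the 8 genes on the lower side were Tmem156, Cyp11a1, Foxj1, Iqcd, Ephx1, Pip5k1bos, Rabggta and Fam81b. Foxj1, a transcription factor that drives genes of motile cilia, was at 84.8 ± 6.61 CPM in controls and 61.9 ± 5.79 CPM with ethanol, a log2 fold change of -0.46 (SE 0.08, edgeR adjusted p = 0.127). Ephx1, the microsomal epoxide hydrolase, was at 68.4 ± 3.34 and 49.7 ± 5.46 CPM. Log2 fold changes were -0.52 for Tmem156, -0.38 for Iqcd, -0.72 for Pip5k1bos, -0.41 for Rabggta, a subunit of the enzyme that adds geranylgeranyl groups to Rab proteins, and -0.36 for Fam81b. The uncharacterised gene 1700036G14Rik, named after its values were seen, had a smaller p than any of these 8 (edgeR adjusted p = 0.0586), at 8.46 ± 0.25 CPM in controls and 4.39 ± 0.49 CPM with ethanol.

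Of the 38 gene lists, camera with a preset correlation between genes called 14, with 9 higher and 5 lower in the ethanol-fed testes. With an estimated correlation it called 0, with 5 lists at an unadjusted p under 0.05. The rotation test fry, which asks whether a list moves one way by itself, called 5 lists, those of Sertoli cells, meiosis, peritubular myoid cells, antioxidant response and autophagy, each with an adjusted p of 0.0333. Counts of members past an edgeR adjusted p of 0.05 were 0 in every list over all genes, so the counts given below are those adjusted over the list alone. That adjustment does not correct for the number of lists. Of all tested genes 13.3% had an unadjusted p under 0.05 by edgeR, so some members may pass through this background alone. A lone member that passes is therefore weak evidence of a difference.

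**Figure D1:**
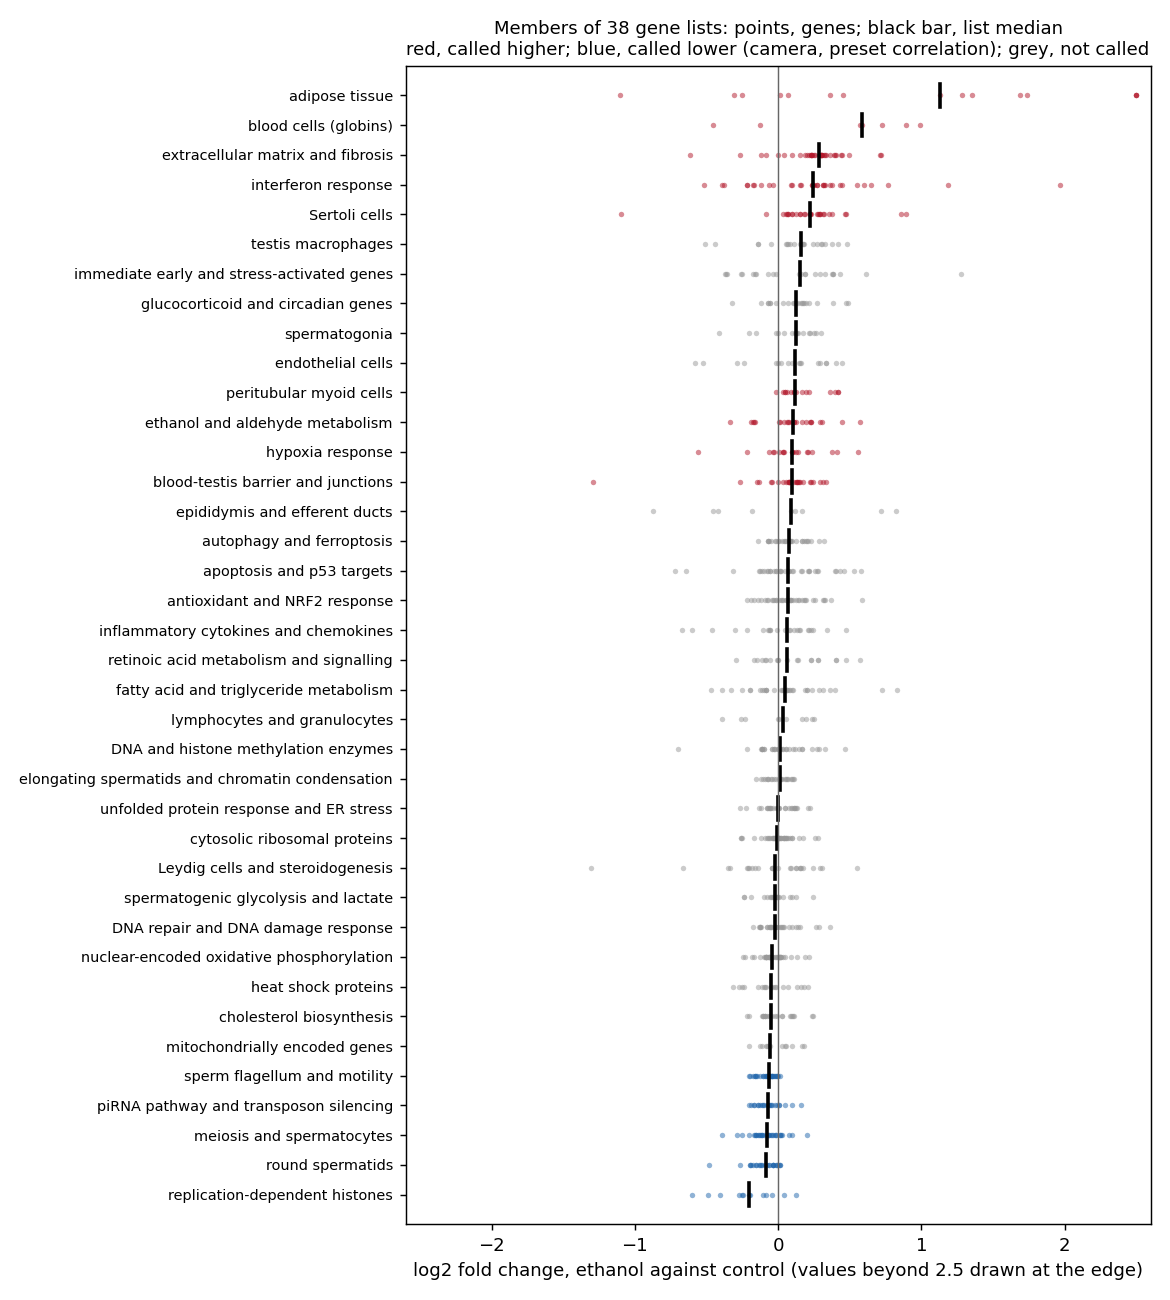
Log2 fold change (ethanol against control, x axis) of the tested members of 38 gene lists (points), with the median of each list as a black bar. The 9 lists called higher by camera with a preset correlation are red and the 5 called lower are blue; the Sertoli median lies at 0.22 and the meiosis median at -0.07.

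In the Sertoli cell list 29 of 31 members were above 0 (camera adjusted p = 2.28e-10; adjusted p = 0.278 with an estimated correlation). Of its members, 14 passed adjusted over the list alone, all higher. Cst9, a cystatin secreted by Sertoli cells, was at 100.2 ± 3.27 CPM in controls and 124.9 ± 8.29 CPM with ethanol, and Cst12 at 57.4 ± 4.46 and 74.4 ± 5.92 CPM. Log2 fold changes were 0.86 (SE 0.21) for the homeobox gene Rhox8 and 0.47 (SE 0.11) for transferrin, Trf. Kitl, the ligand of the Kit receptor on spermatogonia, had a log2 fold change of 0.32 (SE 0.08). The 3 ethanol libraries were above the 3 controls for 16 members. The most negative member was Amh at -1.09 (SE 0.47), which was present at 0.570 ± 0.249 CPM in controls. The panel genes of this list overlapped between the diets. Their log2 fold changes were 0.23 (SE 0.15) for Sox9, 0.06 (SE 0.10) for Inhbb, 0.06 (SE 0.27) for Gdnf and -0.09 (SE 0.21) for Fshr.

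Other lists of the tubule wall and its junctions moved the same way by less. In the list of peritubular myoid cells, the contractile cells around the tubule, 15 of 16 members were above 0 with a median of 0.12 (camera adjusted p = 0.00971; adjusted p = 0.346 with an estimated correlation). Its 1 member that passed adjusted over the list alone was Pdgfra, at 22.5 ± 2.10 CPM in controls and 30.0 ± 3.34 CPM with ethanol. In the list of blood-testis barrier and junction genes, 22 of 28 members were above 0 with a median of 0.10 (camera adjusted p = 0.0275; adjusted p = 0.358 with an estimated correlation). The integrin Itgb1, with a log2 fold change of 0.29 (SE 0.06), was its 1 member to pass adjusted over the list alone, while F11r stood at 0.34 and Cdh1 at -1.29. The junction call ended without control library 1 (median 0.07, adjusted p = 0.0817), 2 (0.10, 0.0512) or 3 (0.105, 0.0622). It also ended without ethanol library 1 (0.12, 0.0769) or 3 (0.06, 0.205), and with GC and length offsets (0.07, 0.0622).

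Extracellular matrix genes formed the list with the second lowest p by camera with the preset correlation, though not with the estimated correlation or by fry. Of 37 members, 32 were above 0 (camera adjusted p = 1.34e-08; adjusted p = 0.346 with an estimated correlation), and 8 passed adjusted over the list alone, all higher. The matrix score was 0.283 in ethanol library 1, which also had the highest adipose score, and -0.0109 and 0.0693 in ethanol libraries 2 and 3, against -0.162 to -0.0677 in controls. Without ethanol library 1 the median was 0.20 (camera adjusted p = 0.000463). Decorin, Dcn, was at 41.5 ± 1.49 CPM in controls and 56.4 ± 4.69 CPM with ethanol, with a log2 fold change of 0.44 (SE 0.08). The metalloproteinase inhibitor Timp2 had a log2 fold change of 0.30 (SE 0.06), the laminin chain Lamb1 0.39 (SE 0.10) and the metalloproteinase Mmp2 0.72 (SE 0.18). The list holds matrix proteases and their inhibitors as well as collagens, and the fibrillar collagen genes Col1a1, at 5.86 ± 1.11 and 8.27 ± 2.71 CPM, and Col1a2, at 26.8 ± 2.10 and 35.4 ± 8.86 CPM, did not pass adjusted over the list alone.

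The lists of meiosis, round spermatids, the flagellum and the piRNA pathway lay below other genes, with small shifts shared by most members. In the list of meiosis and spermatocytes 25 of 32 members were below 0 (camera adjusted p = 0.00128; adjusted p = 0.346 with an estimated correlation), and 3 passed adjusted over the list alone, all lower. Rec8, a cohesin of meiotic chromosomes, had a log2 fold change of -0.39 (SE 0.08), and Ybx2, which binds stored germ cell messenger RNAs, was at 480.3 ± 22.4 CPM in controls and 393.6 ± 35.5 CPM with ethanol. The third was Piwil1, with a log2 fold change of -0.20 (SE 0.06), and Sycp1 of the synaptonemal complex stood at -0.16 (SE 0.06). In the list of sperm flagellum genes 30 of 31 members were below 0 (camera adjusted p = 0.00142; adjusted p = 0.346 with an estimated correlation), and in the round spermatid list 23 of 26 (camera adjusted p = 0.00142; adjusted p = 0.437 with an estimated correlation), with 0 passing adjusted over either list alone. The sperm calcium channel gene Catsper2 was at 252.7 ± 5.20 CPM in controls and 225.9 ± 4.02 CPM with ethanol, and Tex21 of the round spermatid list at 240.3 ± 10.5 and 209.4 ± 10.5 CPM. The list of piRNA pathway genes, which silence transposons in the germ line, had 18 of 23 members below 0 and a median of -0.07 (camera adjusted p = 0.00613; adjusted p = 0.346 with an estimated correlation). Of its members, 0 passed adjusted over the list alone, and Tdrd5 stood at -0.19 (SE 0.06) and Tdrd7 at -0.17 (SE 0.05). On log2(TPM + 1) the piRNA median was -0.0089 and the call was lost (0.106), where the median of all genes was 0.044. With GC and length offsets the medians were -0.13 for piRNA and -0.12 for the flagellum. The flagellum median was -0.10 without ethanol library 1 and -0.05 without ethanol library 3 (camera adjusted p = 0.0353).

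The earliest and the latest germ cell stages were not called. The spermatogonia list had a median of 0.13 (camera adjusted p = 0.812), with Id4, a marker of spermatogonial stem cells, at 32.2 ± 1.09 CPM in controls and 24.1 ± 2.77 CPM with ethanol and the only member to pass adjusted over the list alone. The list of elongating spermatids had a median of 0.012, while camera's direction was lower (adjusted p = 0.818), with log2 fold changes of -0.05 (SE 0.07) for protamine 1, Prm1, and 0.11 (SE 0.09) for the transition protein Tnp1; the sign of Prm1 turned, within 0.01 of 0, on the TPM scale, where the median of all genes is also higher, with GC and length offsets, with the term for length class, and without control library 3 or ethanol library 1. Replication-dependent histone genes fell as a list, with 11 of 13 members below 0 and a median of -0.20 (camera adjusted p = 0.0352; adjusted p = 0.716 with an estimated correlation), and 0 passed adjusted over the list alone. H2ac4, of the smallest p in that list, had a log2 fold change of -0.41 (SE 0.19). That call ended without control library 3 (median -0.06, adjusted p = 0.387), without ethanol library 1 (-0.10, 0.683) or 2 (-0.14, 0.144), with GC and length offsets (-0.14, 0.295), with the term for length class (-0.07, 0.55), with the stricter filter (-0.20, 0.0737) and on log2(FPKM + 0.1) (-0.19, 0.0511). The median moved to -0.31 without control library 2 and -0.45 without ethanol library 3.

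**Figure D2:**
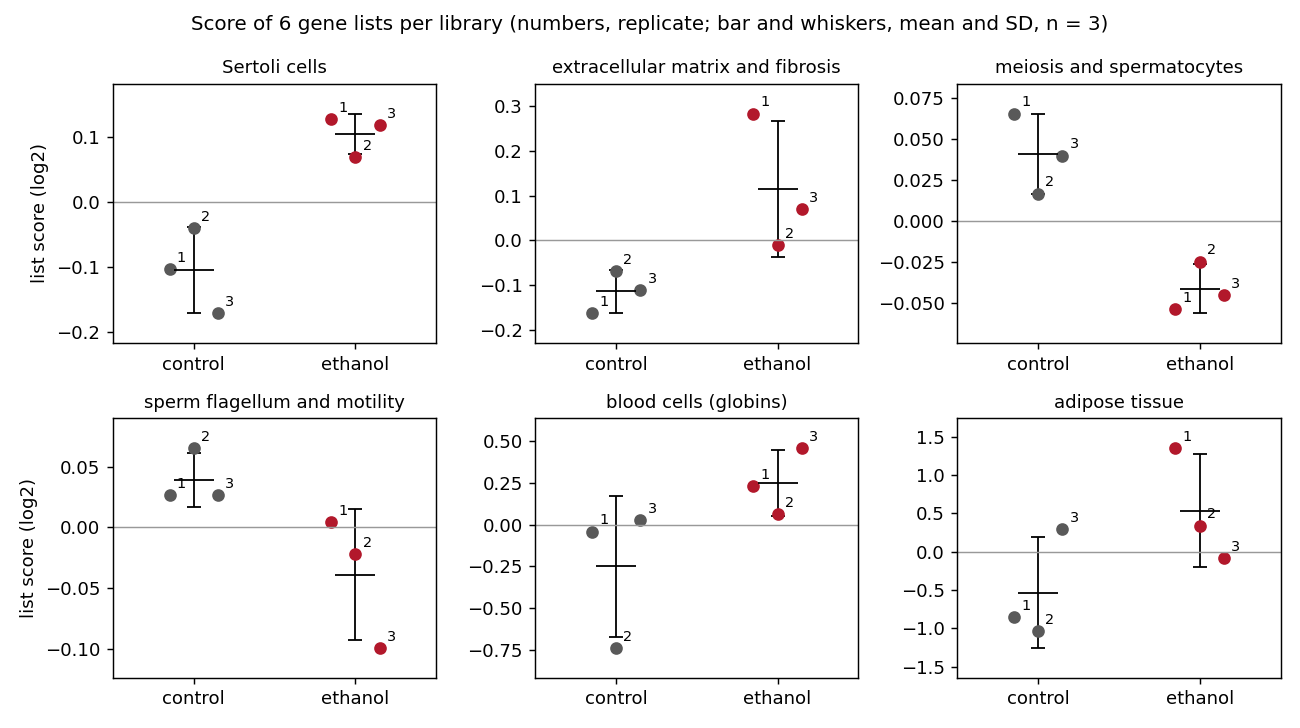
Score of 6 gene lists in each library (y axis, mean over the members of log2 CPM minus the gene's mean over all 6 libraries), with the replicate number beside each point and the mean and SD of 3 libraries per diet as bar and whiskers. Sertoli scores lie between 0.0693 and 0.127 with ethanol and between -0.171 and -0.0399 in controls, while the adipose score is highest in ethanol library 1, at 1.35.

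The Leydig cell list, of the cells that make testosterone, was not called (median -0.02, camera adjusted p = 0.424), and its members went both ways. On the lower side 3 of 26 members passed adjusted over the list alone, and 2 on the higher side. The lower genes were Cyp11a1, Cyp17a1 and Hsd17b3, which encode enzymes for the start, the middle and the last step of testosterone synthesis. Cyp11a1 (Gene ID 13070; chromosome 9, 57998024 to 58027031 on mm10) was at 64.8, 67.9 and 41.5 CPM in the control libraries and 21.9, 33.1 and 15.5 CPM in the ethanol libraries (edgeR p adjusted over the list alone, 0.00392). Cyp17a1 was at 137.8 ± 11.8 CPM in controls and 86.8 ± 35.0 CPM with ethanol, where ethanol library 2 was at 126.8 CPM, within the control range. Without that library its log2 fold change moved from -0.67 (SE 0.20) to -1.05 (SE 0.10) and passed over all genes (edgeR adjusted p = 0.0262). The Leydig list was then called lower (camera adjusted p = 0.0128). With any other library left out, Cyp17a1 lay between -0.74 and -0.48 and did not pass. The list was called in only 1 of the 6 fits without 1 library. Hsd17b3 was at 15.2 ± 0.43 and 12.1 ± 0.37 CPM, a log2 fold change of -0.33 (SE 0.09). The higher members were Hsd3b6, at 44.7 ± 3.27 and 65.5 ± 15.2 CPM, and the nuclear receptor Nr5a1, at 23.4 ± 0.84 and 28.6 ± 2.38 CPM, which is also in the Sertoli list. Log2 fold changes were 0.15 (SE 0.08) for Hsd3b1, 0.12 (SE 0.16) for the cholesterol carrier Star, -0.04 (SE 0.08) for the Leydig hormone Insl3 and -0.04 (SE 0.18) for the luteinizing hormone receptor Lhcgr. The sign turned without ethanol library 2 for Star (-0.14), without control library 2 or ethanol library 3 for Lhcgr (to at most 0.15), and for Insl3 without ethanol library 1 (0.019), on the TPM scale, with the term for length class and with GC and length offsets (0.12). Fdx1, which carries electrons to Cyp11a1, stood at -0.22 (SE 0.08).

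**Figure D3:**
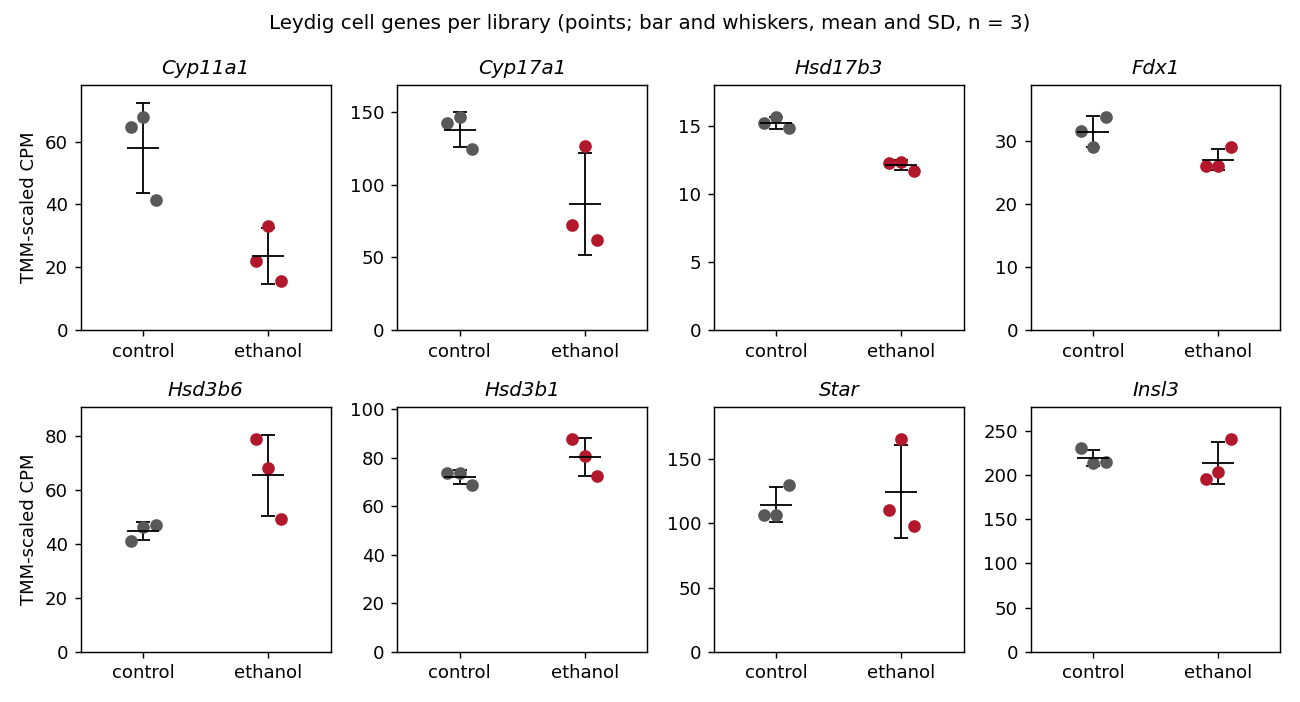
TMM-scaled CPM (y axis, from 0) of 8 Leydig cell genes in each library (points), with the mean and SD of 3 libraries per diet as bar and whiskers. Cyp11a1 and Hsd17b3 lie lower in all 3 ethanol libraries, Cyp17a1 in 2 of them, and Insl3 overlaps between the diets.

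The list of ethanol and aldehyde metabolism rose, with 19 of 24 members above 0 and a median of 0.10 (camera adjusted p = 0.0352, and 0.346 with an estimated correlation). It also holds enzymes of aldehydes other than acetaldehyde, so its shift is not one of ethanol oxidation alone. The 2 members that passed adjusted over the list alone were higher. Aldh2, the mitochondrial enzyme that oxidises acetaldehyde, was at 70.5 ± 4.63 CPM in controls and 87.2 ± 5.95 CPM with ethanol, and Aldh1a3, which makes retinoic acid, at 3.86 ± 0.46 and 5.72 ± 0.37 CPM. Log2 fold changes were 0.23 (SE 0.08) for Aldh1a1, -0.17 (SE 0.06) for Aldh1a2, 0.45 (SE 0.26) for alcohol dehydrogenase Adh1 and 0.07 (SE 0.13) for catalase, Cat. The sign of Cat turned without ethanol library 1 (-0.023) and with the term for length class (-0.036). Adh1 was at 11.8, 13.0 and 4.97 CPM in ethanol libraries 1, 2 and 3 and at 7.06 to 7.62 CPM in controls. Cyp2e1, the ethanol-inducible cytochrome, was too low to be tested. The call of this list ended without control library 1 (adjusted p = 0.056), ethanol library 1 (0.105) or ethanol library 2 (0.0668), and with the term for length class (0.0923). The retinoic acid list, which shares the Aldh1a genes, was not called (median 0.06, camera adjusted p = 0.289); 1 member, Aldh1a3, passed adjusted over the list alone, and Dhrs3 stood at 0.41 (SE 0.12).

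The hypoxia response list also rose, with 15 of 20 members above 0 and a median of 0.10 (camera adjusted p = 0.0352; adjusted p = 0.346 with an estimated correlation). The 3 members that passed adjusted over the list alone were higher. These were Pdk1, a kinase that inhibits pyruvate dehydrogenase, the regulator Hif1a and the vascular growth factor Vegfa. Pdk1 was at 20.8 ± 0.36 CPM in controls and 27.7 ± 1.28 CPM with ethanol. Hif1a stood at 0.24 (SE 0.07) and Vegfa at 0.56 (SE 0.16) on the log2 scale. The call ended without control library 1 (adjusted p = 0.0961) or 2 (0.189), without ethanol library 2 (0.148) or 3 (0.181), and with GC and length offsets (0.0634). The interferon response list was called higher, with 24 of 34 members above 0 and a median of 0.25 (camera adjusted p = 0.0387; adjusted p = 0.714 with an estimated correlation). Adjusted over the list alone, 2 members passed, both higher: Iigp1, at 1.64 ± 0.31 CPM in controls and 3.74 ± 1.07 CPM with ethanol, and Rsad2, at 0.205 ± 0.089 and 0.797 ± 0.458 CPM. The interferon score was 0.414 in ethanol library 2 and between -0.124 and -0.0293 in the other libraries. Without ethanol library 2 the median was -0.02 (camera adjusted p = 0.825), and the call also ended without control library 1 (0.0834) or 3 (0.0937). It ended too with total counts only (0.0643), the stricter filter (0.0772), limma-voom (0.0656), the term for length class (0.215) and limma-trend on each of 4 log scales (0.0928 to 0.155).

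Transcripts of blood and fat, which a piece of testis can carry, differed between the diets too. The blood cell list rose, with 5 of 7 members above 0 and a median of 0.59 (camera adjusted p = 9.24e-05; adjusted p = 0.358 with an estimated correlation), and 5 passed adjusted over the list alone, all higher. Its score was -0.739 in control library 2, -0.042 and 0.0288 in the other controls and 0.0628 to 0.458 with ethanol, and without control library 2 the median was 0.43 (camera adjusted p = 0.00246). The beta globin gene Hbb-bs was at 9.43 ± 3.99 CPM in controls and 18.8 ± 1.93 CPM with ethanol. Alas2 is a member of the same list but did not follow the globin gene among controls. In control libraries 1, 2 and 3 Hbb-bs was at 12.6, 4.94 and 10.8 CPM, and Alas2 at 17.0, 16.3 and 16.4 CPM. The adipose list was called higher with a median of 1.13 (camera adjusted p = 0.00753; adjusted p = 0.671 with an estimated correlation). Adjusted over the list alone, 5 members were higher and 1, Thrsp, lower, but the 3 ethanol libraries lay above the 3 controls for only 2 of 15 members. Adipsin, Cfd, was at 12.3 CPM in ethanol library 1, 3.36 and 0.609 CPM in ethanol libraries 2 and 3, and 0, 0 and 1.29 CPM in the controls. Fabp4, a fatty acid binding protein of adipocytes, was at 10.0 CPM in ethanol library 1 and at most 2.04 CPM in the other 5. The adipose call ended without ethanol library 1, where the median was 0.33 (adjusted p = 0.184), and without control library 2 (adjusted p = 0.14). With the stricter filter the median was 0.46, and limma-trend on each of 4 log scales did not call the list (0.0672 to 0.111).

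The lists of macrophages, endothelial cells, lymphocytes and granulocytes, and epididymis and efferent ducts were not called by camera in the main comparison. That comparison used the filtered, TMM-scaled counts of all 6 libraries without offsets or added terms. Macrophage genes had a median of 0.16 (camera adjusted p = 0.0913, with 0.0414 without control library 2 and 0.0358 with GC and length offsets), with the scavenger receptor Mrc1 at 55.4 ± 1.16 CPM in controls and 68.3 ± 3.61 CPM with ethanol, Lyz2 at 0.33 (SE 0.09) and the complement gene C1qa at -0.44 (SE 0.12) on the log2 scale. Each of these 3 passed adjusted over the list alone. Medians were 0.12 for endothelial cells (camera adjusted p = 0.558), 0.03 for lymphocytes and granulocytes (0.786) and 0.09 for epididymis and efferent ducts (0.636), where camera's direction was lower for the last 2 lists. Foxj1, a member of the epididymis list because efferent ducts are ciliated, was its 1 member to pass adjusted over the list alone.

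Lipid and metabolic lists were not called in that same comparison, though single members differed. The list of fatty acid and triglyceride metabolism had a median of 0.05 (camera adjusted p = 0.558), with 3 members higher and 2 lower adjusted over the list alone. The desaturase Fads2 was at 90.7 ± 5.72 CPM in controls and 69.0 ± 7.70 CPM with ethanol, Cpt1a, which brings fatty acids into mitochondria, at 41.0 ± 2.91 and 51.1 ± 0.96 CPM, and the fatty acid transporter Cd36 at 21.5 ± 4.04 and 35.5 ± 8.51 CPM. Log2 fold changes were 0.40 (SE 0.09) for Fabp3 and -0.33 (SE 0.08) for the lipid droplet gene Plin2. Medians were -0.05 for cholesterol biosynthesis (camera adjusted p = 0.558), -0.02 for spermatogenic glycolysis (0.5), -0.04 for nuclear-encoded oxidative phosphorylation (0.111) and -0.06 for mitochondrially encoded genes (0.812, with camera's direction higher). The oxidative phosphorylation list was called lower without control library 2 (0.00848) and without ethanol library 3 (0.0155).

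Stress lists were not called by camera in that comparison of filtered, TMM-scaled counts either, but fry called those of the antioxidant response and of autophagy (adjusted p = 0.0333 each). Camera called the antioxidant list with GC and length offsets (0.02) and on log2(FPKM + 1) (0.0253) and log2(TPM + 1) (0.0374), and the autophagy list in 6 settings (0.0253 to 0.0459). Medians were 0.07 for the antioxidant response (camera adjusted p = 0.102), -0.0029 for the unfolded protein response (0.818), -0.05 for heat shock proteins (0.289, and 0.0426 without ethanol library 3), 0.07 for apoptosis and p53 targets (0.128) and 0.06 for inflammatory cytokines (0.812). They were 0.08 for autophagy and ferroptosis (0.0736), -0.02 for DNA repair (0.818), 0.15 for immediate early genes (0.812) and 0.13 for glucocorticoid and circadian genes (0.0662, with 0.0431 without the filter on low counts, 0.00947 without control library 2 and 0.0289 without ethanol library 2). Within these lists Hspa2, a chaperone of spermatocytes, was at 1279 ± 29.0 CPM in controls and 1073 ± 80.2 CPM with ethanol, and Klf4, a factor of round spermatids and Sertoli cells, at 93.2 ± 3.85 and 77.9 ± 2.25 CPM. Both passed adjusted over their list alone. Genes of DNA and histone methylation enzymes had a median of 0.01 (camera adjusted p = 0.982), and 1 member, Dnmt3l, a cofactor of DNA methyltransferases, passed adjusted over the list alone at 10.6 ± 0.44 CPM in controls and 6.51 ± 1.40 CPM with ethanol. Ribosomal protein genes had a median of -0.0042 (camera adjusted p = 0.818, and 0.0306 in the lower direction without control library 2).

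Of the panel of 27 genes fixed beforehand, 26 could be tested; 2 had an unadjusted p under 0.05 on the higher side and 3 on the lower side, and 0 passed edgeR's test over all genes. DESeq2 called Aldh2 (adjusted p = 0.0306) and Cyp11a1 (0.0385). The other 21 had a larger p, among them the stress gene Hmox1 at 0.09 (SE 0.12).

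No list call held with an estimated correlation, so the 14 calls by camera rest on the preset correlation of 0.01 between genes of a list. Of these lists, fry, which uses no preset correlation, also called those of Sertoli cells, meiosis and peritubular myoid cells. The limma-trend test on log2(TPM + 0.1) called 5 lists and on log2(FPKM + 0.1) 6; neither called the lists of meiosis, piRNA, ethanol metabolism, junctions or hypoxia.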

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

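The offsets for GC content and length, the term for length class, the protein-coding genes alone and the estimated correlation without ethanol library 1 were chosen after the result was seen. The sign of the log2 fold change held in all 22 refits for 13 of the 26 panel genes and turned at least once for 13.

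The number of genes called depended on the tool and its settings. Under edgeR's other settings, 2 genes were higher with upper-quartile scaling and 2 with the filter of 1 CPM in 3 libraries, in both cases Nmnat3 and Gm41370. Limma-voom called 3 higher (Nmnat3, Gm41370 and Smco3) and 2 lower (1700036G14Rik and Akr1b7); Smco3 had 0 counts in the 3 controls and Akr1b7 in the 3 ethanol libraries. DESeq2 called 203 higher and 127 lower, with 2796 genes at an unadjusted p under 0.05. GC and length offsets gave 5 higher and 2 lower among 17357 genes, and the length class of the library as a term 16 higher and 4 lower, Cyp11a1 among the latter (adjusted p = 0.0137). A threshold of 0.1 gave 4 higher and 1 lower. RLE factors, total counts, no filter, removal of mitochondrial and globin genes, protein-coding genes alone and limma-trend on the 4 log scales gave 0 in both directions. The cause was not tested. Simulated genes changed by 1.5-fold were called in 66% of cases and fewer of those changed by less. The simulation had no structure among libraries and held many other changed genes, so these rates may be too high for the real data. Single genes with differences as small as those of most list members were therefore mostly not detectable with these libraries. Depth and number of libraries were not varied. With 1 library left out, 0 to 1 genes were higher and 0 to 2 lower: Gm46809 without control library 1, Gm4258 without control library 2, LOC115488130 without control library 3, Nmnat3 and Cyp17a1 without ethanol library 2, and Npcd, Nptxr and 1190005I06Rik without ethanol library 3. Genes named in this paragraph outside the rule were chosen after their values were seen.

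With the replicate number as a replicate block, edgeR called 5 genes higher and 10 lower, Cyp11a1 among them (adjusted p = 0.00126), and camera 14 lists. Deviations of same-numbered libraries correlated across genes at -0.058, 0.0029 and 0.13 for numbers 1, 2 and 3, and only the libraries of number 3 correlated best with their own number, so the numbers were not taken as pairs.

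The number of lists called was 5 by fry, 6 by limma-trend on log2(FPKM + 0.1), 5 on log2(TPM + 0.1), and 0 by camera with an estimated correlation, with or without ethanol library 1. It was 10 to 15 with 1 library left out and 12 to 17 under the other settings. Sertoli, extracellular matrix and myoid lists were called in each of 21 refits with the preset correlation, round spermatid and flagellum lists in 20 and meiosis and piRNA lists in 18. The blood list was called in each of the 20 in which it could be tested, which leaves out the fit without globin genes. Calls ended in more fits for the adipose list (15 of 21 kept), ethanol metabolism (15), hypoxia (14), histones (14), junctions (13) and interferon (10).

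Signs turned for panel genes not past the threshold. On log2(TPM + 1) and log2(TPM + 0.1), the log2 fold change was 0.011 and 0.011 for Insl3, 0.026 and 0.027 for Sycp3, 0.023 and 0.023 for Acrv1, and 0.0091 and 0.0091 for Prm1. The medians of all genes on these scales, 0.044 and 0.058, lay above each of these values, which is in line with a shift of the scale common to most genes. For Trp53 it was 0.0098 with total counts only, 0.041 and 0.060 on the FPKM scales and 0.076 and 0.093 on the TPM scales. GC and length offsets gave 0.12 for Insl3, 0.020 for Sycp3, 0.0018 for Prm1 and -0.014 for Hspa5. The length class term gave -0.036 for Cat, 0.0094 for Insl3, -0.15 for Gdnf and 0.0037 for Prm1.

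With 1 library left out, the log2 fold change ranged from -0.023 to 0.18 for Cat, -0.14 to 0.27 for Star, -0.14 to 0.019 for Insl3, -0.18 to 0.15 for Lhcgr, -0.24 to 0.013 for Fshr, -0.0066 to 0.14 for Inhbb and -0.13 to 0.26 for Gdnf. It ranged from -0.21 to 0.37 for Stra8, -0.13 to 0.032 for Sycp3, -0.089 to 0.027 for Acrv1, -0.11 to 0.0097 for Prm1, -0.014 to 0.028 for Hspa5, -0.10 to 0.15 for Trp53 and -0.070 to 0.19 for Adipoq, an adipose gene outside the panel. The cause was not tested.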

Other observations

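The tests of a lower share of germ cells, of fewer Leydig cells and of adipose tissue carried into a sample were chosen only after the result was seen, as were the length class term and the offsets for GC content and length.

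Some transcripts outside the lists were named after their values were seen. The nuclear long noncoding RNAs Neat1 and Malat1 were at 371 ± 50.6 and 2262 ± 191 CPM in controls and at 567 ± 108 and 2773 ± 225 CPM with ethanol. Neither passed edgeR's test over all genes, while DESeq2 called both (adjusted p = 0.00064 for Neat1 and 0.0387 for Malat1), and edgeR with the length class of the library as a term called Neat1 (0.0148).

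Sertoli and extracellular matrix lists lay above other genes and the meiosis, round spermatid and flagellum lists below them, while the spermatogonia and elongating spermatid lists had medians above 0 and were not called. The elongating median turned to -0.018 without control library 2 and -0.037 without ethanol library 3. The spermatogonia median was 0.058 without control library 1 and 0.057 without ethanol library 1. With offsets for GC content and length, the lower of the Sertoli and matrix medians was 0.198 and the highest camera adjusted p of the meiosis, round spermatid and flagellum lists was 0.0207, which argues against such bias as the whole cause, and without ethanol library 1, which held adipocyte transcripts, the lower of the Sertoli and matrix medians was 0.199. A lower share of germ cells alone would raise all somatic lists alike, yet the Sertoli minus Leydig score was higher with ethanol by 0.275, or 3.29 pooled SDs with no overlap, and by 0.178 without Cyp11a1, Cyp17a1 and Hsd17b3. This was the widest of 4 such comparisons: differences of the Sertoli score minus the myoid (0.0379, or 0.694 SDs), endothelial (0.184, or 1.69) and macrophage (0.0948, or 2.07) scores were smaller and overlapped between the diets. A lower germ cell share together with a change in Leydig or Sertoli cells may therefore contribute and stays open, as does an effect of the diet within the cells.

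Among Leydig cell genes, Cyp11a1, Cyp17a1 and Hsd17b3 lay lower. If fewer Leydig cells were the only cause, the 7 Leydig genes of the panel would fall at least about as far as Hsd17b3. Of the 7, 3 genes, Star, Hsd3b1 and Insl3, lay above it by more than 2 of their SEs. Hsd17b3 was taken as the mark after it was seen to be low, the SE of Hsd17b3 was not counted, and Star stood at -0.14 without ethanol library 2. Fewer Leydig cells together with other changes are therefore not excluded. The highest log2 fold change plus its SE of the 3 genes over the 6 fits without 1 library was -0.211, so no single library carries the direction. A lower level of these enzymes in Leydig cells on the ethanol diet may be the source, and a difference in the time or state of the animals at sampling was not tested.

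Adipocyte transcripts stood out in ethanol library 1, where 10 of the 15 tested members of the adipose list were at their highest of the 6 libraries, but that count restates the observation that prompted it and tests nothing. Adipose tissue carried into that sample may be the source and stays open. Plin4 was at 11.3 CPM there, and Lpl at 7.63 CPM there and at most 2.61 CPM elsewhere. Adipoq, at 13.2 CPM there and 13.6 CPM in control library 3, did not share the excess. Of the list, 7 members have a control mean of at least 1 CPM and 1 is in another list.

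Other groupings of the 6 libraries bear on the counts. There are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 14 lists, the highest of the others 10, and 1 split gave as many lists as the real one, which was the real one. It gave 3343 genes at an unadjusted p under 0.05, the highest of the others 3133, and 1 split, again the real one, gave as many. At an adjusted p under 0.05 the real split gave 0 genes, which 10 of 10 splits reach, and the highest of the others 12. That split set control libraries 1 and 3 and ethanol library 3 against the rest, with 9 lists, which points to a structure of the samples that the labels do not name. Deviations of those 3 libraries correlated across genes with transcript length at -0.28, -0.34 and -0.15, and those of control library 2 and ethanol libraries 1 and 2 at 0.22, 0.33 and 0.21; genes are not independent replicates. With this class, which was defined from these data, as a term, 16 genes were higher and 4 lower, and 12 lists were called.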
